A study of Drosophila melanogaster with 6 samples.

How the data were processed

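RNA was measured in 6 libraries of adult Drosophila melanogaster, 1 for each combination of 2 genotypes and 3 tissues. In the foxo RNAi flies, the Act88F-Gal4 driver, which is active in indirect flight muscle, expressed a hairpin against foxo, a transcription factor repressed by insulin signalling. The control flies carried the same driver crossed to the w1118 strain. The tissues were thorax (labelled as skeletal muscle), gut, and carcass (labelled as fat body, dissected without gut and eggs). Per the labels, the flies were 10 days old, and the protocol places them on a sugar and yeast diet at 2 to 3 days after eclosion for 10 days.

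Per the labels' protocols, total RNA was made into libraries with a stranded total RNA kit. Per the series design text, reads of 50 bases were read from 1 end on an Illumina HiSeq instrument and mapped to Release 6 of the fly genome. The aligner, the counting tool, the annotation version and the strand setting are not given in the sources used here. The authors deposited whole-number read counts per gene, without normalization, for 17609 genes. They also deposited RPKM values, scaled by library total and gene length, in which the length is the whole genomic span of the gene, introns included. Whether reads that map to several places were counted is not given in the sources used here, so genes with near-identical copies are uncertain. The design text gives 7000000 to 12000000 reads per library, and the deposited counts sum to between 13274574 and 34385727.

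Of the genes, 17559 were matched to the RefSeq annotation of Release 6, 13239 by symbol, 4203 by position and 117 by an older name. Counts above 0 were listed for 11216 genes, of which 11198 are protein-coding. Nearly all other genes were listed at 0 counts, but 1197 of the genes at 0 had an RPKM above 0. Multiplying RPKM by length gave whole reads, within 0.001, in 100% of entries, and those reads made up between 0.292 and 0.750% of each library. No mitochondrial genes were listed. Of 1783 coding genes lying wholly inside another coding gene, 0 had any read, against 98.3% of 3876 genes that overlap another in part and 90.1% of 8203 that overlap none. Genes of that kind, among them Pepck, Ilp6, Cyp4g1, sesB and TpnC4, were therefore treated as not measured.

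With 1 library per genotype and tissue there is no replicate check, and no p-value across genes was computed for the genotype comparisons. For each tissue, counts were scaled with TMM factors from its 2 libraries (edgeR 4.0.16 in R 4.3.3). The ratio used 0.5 added to each count, and its 95% interval came from the 2 counts by the exact Clopper-Pearson method (scipy 1.17.1). Intervals and floors cover counting error only, not differences between flies or dissections, and reads copied by PCR are not independent molecules. A gene was called higher or lower in the foxo RNAi library where the 2 libraries held at least 30 reads together, the ratio was at least 2-fold, and the interval bound nearest to equality was at least 1.5-fold. A fold against a library with 0 reads was computed against a floor of 3 counts in that library and is given as a lower bound. Each fold from 0 reads written as "at least" refers to this floor, not to the start of the exact interval. The exact 2-sided interval of the ratio starts below that bound, for vanin-like in thorax at 23.9-fold against 29.7-fold. What the floor is worth follows from the depth of the library. The 3 counts are worth 0.0847 CPM (counts per 1e6 reads) in the foxo RNAi thorax library and 0.213 CPM in the foxo RNAi carcass library.

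Gene lists for pathways, responses and cell types were fixed beforehand. Some genes, such as eloF, Lip4 and AkhR, are on more than 1 list, so results of different lists are not independent. For each list, the median log2 ratio of the members with at least 30 reads was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list with at least 5 measured members was said to stand apart under percentile 1 or over percentile 99. These percentiles describe the libraries and are not tests between genotypes. Numbers of genes called in more than 1 tissue were set beside the number that independent lists of the same sizes would share.

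Tissues were compared with edgeR's quasi-likelihood test over all 6 libraries, with TMM scaling, genes kept by filterByExpr with tissue as the group, genotype as a covariate, and Benjamini-Hochberg adjusted p under 0.05. The 2 libraries of a tissue come from different genotypes, so these p-values measure the spread left after a common genotype term, with 2 residual degrees of freedom. The common biological coefficient of variation was 0.296.

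The tests, thresholds, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named foxo and upd2 always. Per tissue and direction it named the 10 called genes with the largest near interval bound, without genes known only by number, and up to 2 numbered genes. It added up to 4 called members of each list per direction, up to 2 others where a list stood apart, and up to 15 genes called the same way in all 3 tissues. Between tissues it named the 5 genes with the largest fold over both others at 100 CPM or more, and up to 4 members of each cell type list. Lists of photoreceptor markers, Osiris genes, heat shock genes and Hsp70 copies were written after the values were seen.

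The alternatives were scaling by total counts, DESeq2 1.42.0 size factors, the deposited RPKM on the scale log2(value + 0.5), read minimums of 10 and 100, looser and stricter size rules, lists without their most extreme member, and ratios after a loess trend was removed. For tissues they were RLE factors, the DESeq2 Wald test, no expression filter, no genotype covariate, a test against a fold of 2, and each library left out in turn. Alternatives added after seeing the data used reads recovered from RPKM, left out genes at least 5 times as abundant in another tissue together with photoreceptor markers, and left out coding genes that overlap another. Abundance there was the mean CPM, scaled within each tissue, so the cut between tissues is approximate.

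The methods were checked on simulated counts drawn from the real means and library sizes. For the genotype comparisons the draws were Poisson, with counting error only and no spread between flies, dissections or libraries. Their false calls are therefore not an error rate for the real calls. With 200 planted genes, 3-fold differences were recovered at 96.2% in thorax (8877 genes), 95.6% in gut (7851 genes) and 96.0% in carcass (8582 genes), with at most 0.4 false calls on average. For the tissue test the draws were negative binomial with the real dispersions, tissue differences were removed, and 200 genes were changed in gut. The tissue test for thorax against gut, on 9191 genes, recovered 67.2% of 4-fold and 83.0% of 8-fold differences with 12 false calls on average. In the real data 54.6% of genes were called between thorax and gut, so differences that broad were not covered by this check. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.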

Results

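Total RNA profiles were collected from thorax, gut and carcass of flies with flight-muscle RNAi against foxo and of driver controls, with 1 library per genotype and tissue. The control libraries held 17987881 counted reads in thorax, 14532894 in gut and 15621447 in carcass. The foxo RNAi libraries held 34385727, 14227132 and 13274574. The comparisons ask what the expression of a foxo hairpin in flight muscle is accompanied by in muscle itself and in distant tissues that take part in energy storage. No difference between genotypes has a replicate check, and each describes a pair of libraries.

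The targeted gene foxo (chromosome 3R, 14056945 to 14087978, plus strand) had ratios under 1 in the 3 tissues with each scaling, though in gut the interval depended on the scaling. In thorax it had 196 CPM (95% interval 190 to 203) in the control and 141 CPM (137 to 145) in the foxo RNAi library, from 3425 and 4984 reads. The ratio was 0.717 (0.686 to 0.749). In gut the ratio was 0.783 (0.719 to 0.852) from 1143 and 1031 reads, and in carcass 0.763 (0.708 to 0.823) from 1637 and 1192 reads. None of the 3 ratios passed the size rule. The ratio in thorax was near those in gut and carcass, where the driver is not named as active. These values therefore do not show a loss of foxo RNA particular to muscle. The hairpin is itself transcribed from foxo sequence, so its reads can count towards foxo. With total-count scaling the ratios were 0.761 (0.729 to 0.795), 0.921 (0.846 to 1.003) and 0.857 (0.795 to 0.924), so the interval in gut reached equality.

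The gene upd2 (chromosome X, 18240654 to 18243284, minus strand) codes for a secreted leptin-like cytokine. It was 4.91-fold higher in the foxo RNAi thorax library (3.02 to 9.04), from 16 control and 164 foxo RNAi reads, and passed the size rule. On the RPKM scale, which understates low genes, the thorax ratio was 2.75. In gut, upd2 had 24 and 65 reads, a ratio of 2.32 (1.45 to 3.93), and did not pass, though it did with total-count scaling (2.73, 1.71 to 4.62). In carcass it had 8 reads in the control and 0 in the foxo RNAi library, at least 2.54-fold lower against the floor, with a ratio whose interval ends at 0.614, and under the read minimum.

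**Figure D1:**
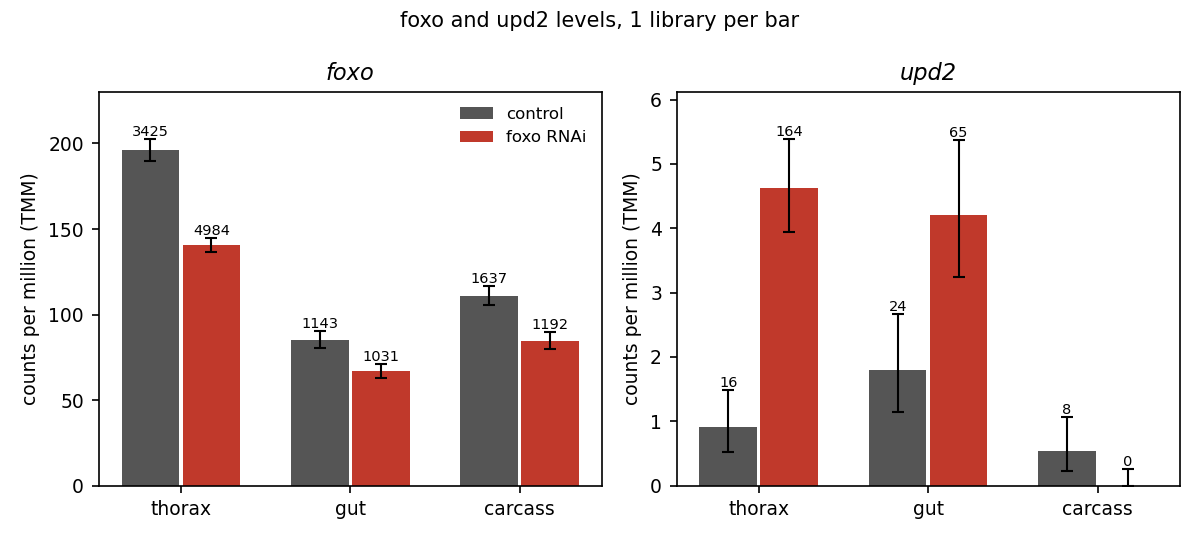
Bars show TMM-scaled CPM of foxo (left) and upd2 (right) in control and foxo RNAi libraries of thorax, gut and carcass, 1 library per bar, with exact 95% counting intervals and read counts above the bars. The foxo bar is lower in each foxo RNAi library, with ratios from 0.717 to 0.783, and upd2 is higher in the foxo RNAi library in thorax (164 reads). Scaling is within each tissue, so bars are not compared between tissues.

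The foxo RNAi thorax library held more transcripts of Hsp70Bb, Muc68D, digestive enzymes and the Turandot stress peptides TotM, TotC and TotA than the control thorax library, and fewer transcripts of several genes of fatty acid oxidation, such as whd, and of Sesn and Thor, both described as Foxo targets. Hsp70Bb, an inducible chaperone gene, had 24 control and 43222 foxo RNAi reads, an 869-fold higher level (596 to 1385). Muc68D, an intestinal mucin gene, was 492-fold higher (363 to 704). Sesn, which codes for the TOR inhibitor Sestrin, was 2.44-fold lower (2.40 to 2.49), and Thor, which codes for the translation repressor 4E-BP, was 2.01-fold lower (1.98 to 2.05). Act88F, the flight muscle actin whose promoter drives the hairpin, was 3.02-fold lower (3.00 to 3.05).

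Of 8887 genes compared in thorax, 316 were higher and 242 lower. The other named genes with the largest differences upward were Muc68E (42.5-fold), mesh (34.1-fold), Peritrophin-15a (35.9-fold), Jon65Aiii (22.6-fold), alphaTry (17.4-fold) and ninaE (23.0-fold), which is the main rhodopsin gene of the eye. The gene vanin-like had 0 control and 181 foxo RNAi reads, at least 29.7-fold higher. The chitinase gene Cht4 went from 1 to 1336 reads, a ratio of 439 whose interval starts at 118. The numbered gene CG14125 was 302-fold higher, and CG15818 had 1 and 2813 reads, a ratio of 924 whose interval starts at 249. Downward, the odorant-binding protein gene Obp99b was 535-fold lower (335 to 989), the alkaline phosphatase gene Alp2 134-fold, Tektin-C 64.9-fold, Mur18B 73.7-fold, GstD5 10.5-fold, and the yolk protein receptor gene yl 13.3-fold. Smvt had 62 and 1 reads, 84.6-fold lower with an interval starting at 21.8. The numbered genes CG8343 and CG10814 were 71.8-fold and 37.8-fold lower.

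In thorax, 2 lipid lists had medians below their random lists, with few members past the size rule, and only 1 of them had a smaller share of reads in the foxo RNAi library. The list for lipolysis and fatty acid oxidation had a median log2 ratio of -0.31 (percentile 0.02), with 4 of 20 measured members lower and 0 higher, and its share of reads was 0.347% in the control and 0.230% in the foxo RNAi library. The members lower were CG5966, a predicted triglyceride lipase gene (6.42-fold), whd, the carnitine palmitoyltransferase that admits fatty acids to mitochondria (2.17-fold), yip2 (2.22-fold) and Thiolase (2.04-fold). Triglyceride synthesis and storage had a median of -0.31 (percentile 0.03), with 3 of 26 members lower, namely eloF (5.51-fold), CG1942 (6.25-fold) and FASN2 (2.58-fold), but its share of reads was higher, 1.47% against 1.16% in the control. Oenocyte genes, which make cuticular hydrocarbons, had a median of -0.43 (percentile 0.28). Among 8 members, FASN3 (5.63-fold), Fad2 (5.40-fold) and eloF, which is also on the triglyceride list, were lower. Without its most extreme member this list no longer stood apart (percentile 1.07), and its share of reads was 0.345% in the control and 0.425% in the foxo RNAi library. Glutathione transferases also stood below, with a median of -0.43 (percentile 0) and GstD5, GstD9 (2.81-fold), GstD3 (2.24-fold) and GstD4 (3.83-fold) lower among 28. The lipophorin receptor gene LpR1 was 5.41-fold lower, but lipoproteins as a list were at -0.07 (percentile 28.7), with 1.48% of reads against 1.04% in the control.

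Glycolysis, glycogen and trehalose genes stood above, with a median of 0.21 (percentile 99.9), 0 of 22 members called and near-equal shares of reads, 1.76% in the control and 1.75% in the foxo RNAi library. Antimicrobial peptides and immune effectors had a median of 0.33 (percentile 100), with 8 of 31 higher, among them AttA (2.69-fold) and Dpt (2.53-fold), and Drsl4 lower (2.34-fold). Haemocyte genes had a median of 0.40 (percentile 99.99) with 0 of 16 called. Of the JAK-STAT receptors and targets, the humoral stress genes TotM (4.76-fold), TotC (3.49-fold) and TotA (2.75-fold) were higher and the complement-like Tep1 5.06-fold lower, with a list median of 0.09 (percentile 85.9). Secreted factors were at 0.13 (percentile 96.6), with upd2 and Pvf2 (3.15-fold) higher. Akh, the adipokinetic hormone gene, was 2.08-fold higher within an insulin, TOR and AKH list at -0.03 (percentile 35.3). The iron carrier Tsf1 was 2.49-fold higher and the larval serum protein Lsp1beta 3.15-fold lower among fat body markers, whose median was -0.12 (percentile 12.6).

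Markers of other tissues moved with the thorax comparison. Digestive enzymes had a median of 1.58 (percentile 100) with 19 of 32 higher, including Jon65Aiv (14.8-fold) and Mal-A1 (13.8-fold). Cuticle genes stood above at 0.64 (percentile 99.98), with the chitin deacetylase genes serp (3.77-fold) and verm (3.41-fold) higher and Cpr49Ab 3.23-fold lower, and were at percentile 86.9 on the RPKM scale. Photoreceptor markers, chosen after values were seen, were higher for 6 and lower for 2 of 12. Heat shock genes stood above at 0.25 (percentile 99.06), a placement that ended with total-count scaling (98.8), with a read minimum of 10 (83.5), without the most extreme member (88.9), after loess (98.95) and on the RPKM scale (71.0). Hsp70Ab, with 0 and 106 reads, was at least 17.4-fold higher against the floor of 3 counts. The Hsp70 copies are near-identical, however, so how reads divide between Hsp70Ab and Hsp70Bb is uncertain.

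Muscle and mitochondrial groups did not stand apart in thorax. Sarcomere genes had a median of 0.06 (percentile 93.3), with Act88F and Zasp52 (2.11-fold) lower among 27. Oxidative phosphorylation was at 0.03 (percentile 84.9) with ND-24 (2.80-fold) and ND-51 (2.10-fold) lower among 36, and the TCA cycle at 0.11 (percentile 95.8). Foxo targets were at -0.19 (percentile 2.15) with Sesn and Thor the 2 members lower among 17. With total-count scaling the calls of Thor (log2 -0.92), Thiolase (-0.94), ND-51 (-0.99), Zasp52 (-0.99) and Cpr49Ab (-1.61) ended. The remaining lists in thorax were enteroendocrine peptides at -0.09 (percentile 19.0), intestinal epithelium at 0.02 (46.5), the circadian clock at 0.07 (76.8), autophagy at -0.06 (23.4), proteasome at -0.06 (24.3), ribosomal proteins at 0.00 (84.9), cytochrome P450s at -0.05 (15.6), antioxidant genes at -0.05 (33.1), ovary and eggshell at -0.28 (4.24), female tract at 0.23 (84.2), neurons at -0.15 (4.06) and Malpighian tubule at 0.03 (56.0). Leaving out 775 genes more abundant in other tissues, a choice made after seeing the data, left 143 higher genes in place of 316 and 187 lower in place of 242, so 43.3% of calls were higher in place of 56.6%. Sesn, whd, Thiolase, mesh, Pvf2, Mal-A1, ND-51 and Zasp52 overlap another coding gene, so their counts are uncertain.

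**Figure D2:**
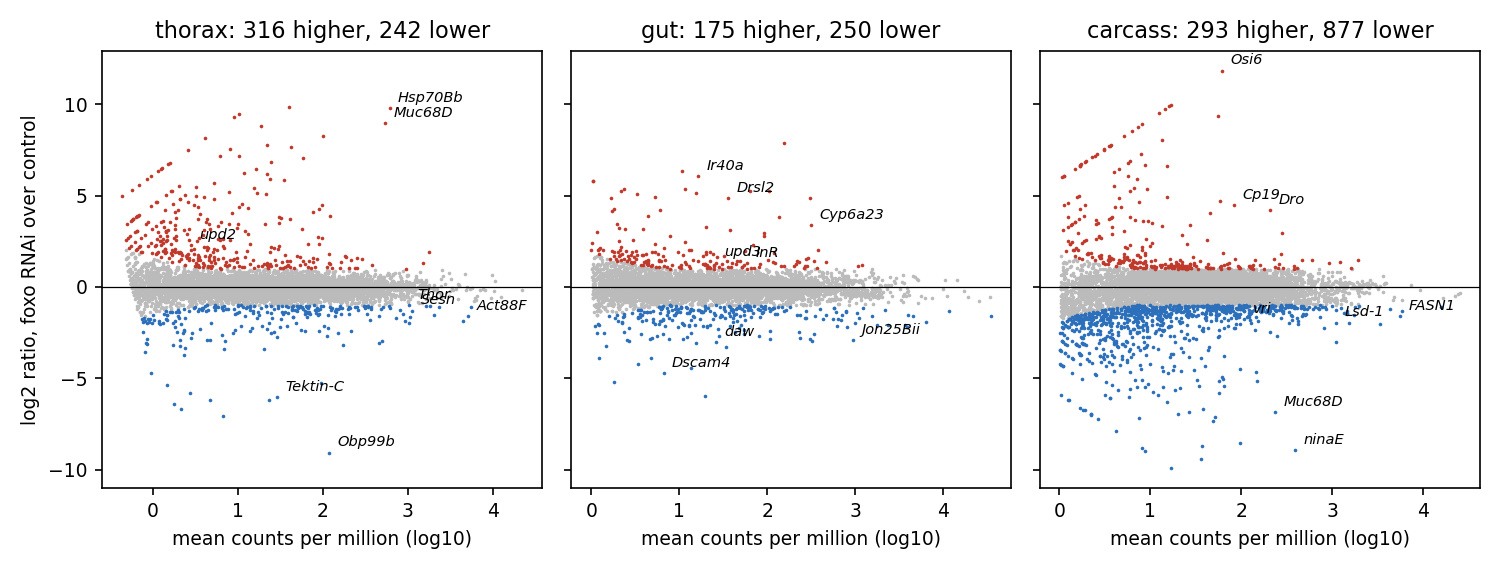
Each point is a gene with at least 30 reads, placed by its mean CPM (log10 axis) and its log2 ratio of foxo RNAi over control, for thorax, gut and carcass with 1 library per genotype. Red and blue points passed the size rule, and the carcass panel has the most genes lower, 877 against 293 higher.

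In gut, the foxo RNAi library held more transcripts of InR, ImpL2 and the ligands vn and upd3, and fewer of digestive proteases and of the lipid storage gene Lsd-1. InR, the insulin receptor, was 2.45-fold higher (2.20 to 2.74), ImpL2, a secreted insulin antagonist, 2.11-fold (1.89 to 2.37), vn, an EGF receptor ligand, 3.78-fold (2.82 to 5.22, but not past the size rule on the RPKM scale, at a log2 of 0.72), and the cytokine upd3 2.52-fold (2.14 to 2.98). The activin ligand gene daw was 8.11-fold lower (6.51 to 10.3) and the neuropeptide gene CNMa 5.49-fold lower (4.73 to 6.43). The serine protease gene Jon25Bii was 7.53-fold lower (7.27 to 7.81), and Lsd-1, the lipid droplet perilipin, 3.05-fold lower (2.71 to 3.45).

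Of 7866 genes compared in gut, 175 were higher and 250 lower, so 41.2% of calls were higher. With total-count scaling the median of all genes moved up by 0.235 (log2) and 65.9% of calls were higher, and on the RPKM scale 61.4% were. The largest differences upward were in the ionotropic receptor gene Ir40a (66.7-fold), the antifungal peptide family member Drsl2 (28.6-fold), lcs (14.1-fold), Cyp6a23 (10.5-fold), Send1 (2 and 54 reads, 18.9-fold, 6.18 to 198), Cyp6t3 (9.23-fold), Try29F (5.45-fold), Hs3st-A (5.92-fold) and kon (4.10-fold). Cyp12d1-d had 0 and 32 reads, at least 9.26-fold higher. The numbered genes CG32302 and CG13947 were 238-fold and 80.7-fold higher, the latter from 3 control reads (31.9 to 458). Downward, Dscam4 was 26.5-fold lower, Tektin-C 18.3-fold, Alp2 7.65-fold, IntS12 6.71-fold, mwh 6.31-fold, Alp4 5.35-fold and Jon99Cii 4.62-fold, with CG3264 62.5-fold and CG11893 21.8-fold lower.

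Digestive enzymes had a median of -0.55 in gut (percentile 0), with 15 of 42 lower, among them Jon99Ciii (4.23-fold) and Jon25Biii (3.77-fold), and Ser6 2.24-fold higher. Triglyceride synthesis and storage had a median of -0.58 (percentile 0) with Lsd-1, eloF (3.54-fold) and CG1942 (2.02-fold) lower among 26. Lipolysis and fatty acid oxidation was at -0.28 (percentile 0.21) and lipoproteins at -0.29 (percentile 0.755), each with 0 members called. The share of reads from lipoprotein genes was 0.137% in the control and 0.157% in the foxo RNAi library, and the placement ended without its most extreme member (percentile 3.75) and on the RPKM scale (1.22). Glycolysis genes were at -0.31 (percentile 0.21) with Tps1, the trehalose synthase, 2.23-fold lower among 22, although their share of reads was 0.561% in the control and 0.638% in the foxo RNAi library. Ribosomal proteins were at -0.35 (percentile 0) with 0 of 82 called, and proteasome genes at 0.16 (percentile 99.4) with 0 of 30 called.

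Markers of other cell types also moved in gut. Fat body markers were at -0.76 (percentile 0) with Lsp1beta 3.54-fold lower among 13, oenocyte genes at -0.87 (percentile 0) with Fad2 (4.13-fold), eloF and FASN3 (2.88-fold) lower, and Malpighian tubule genes at -0.59 (percentile 0) with 4 of 17 lower, such as the transporters Oatp58Dc (2.94-fold) and ZnT35C (2.68-fold), and cv-2 2.35-fold higher. Sarcomere genes were at 0.49 (percentile 100), with Act79B (3.18-fold) and the titin-like bt (2.02-fold) higher among 24. Enteroendocrine peptides were at 0.25 (percentile 99.6) with ITP 2.65-fold higher among 12, and neurons at 0.55 (percentile 99.3) with 0 of 9 called. Female tract genes were at 0.72 (percentile 99.3), with Send1, CG17239 (1 and 71 reads, 41.4-fold, 10.7 to 2467) and CG32834 (14.98-fold) higher among 7. With a read minimum of 100, enteroendocrine (98.9) and neuron (98.1) genes no longer stood apart, and female tract genes kept 4 members, too few to place. Enteroendocrine genes also lost it without the most extreme member (98.8), and on the RPKM scale they were at 81.6 and neurons at 89.4.

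Detoxification genes were called in both directions in gut. Glutathione transferases GstD2 (3.35-fold), GstD5 (3.15-fold), GstD9 (2.65-fold) and GstD8 (2.36-fold) were higher and GstE10 2.28-fold lower, with a list median of 0.13 (percentile 97.8). Of 54 cytochrome P450 genes, 4 were higher and 9 lower, Cyp4d8 by 4.40-fold and Cyp6g1 by 2.75-fold, with a median of -0.09 (percentile 5.61). Foxo targets were at -0.13 (percentile 14.8), with InR and ImpL2 the members called. The heat shock genes Hsp68 (2.26-fold), Hsp27 (2.29-fold) and Hsp23 (2.17-fold) were lower, with a list median of -0.15 (percentile 13.8). With total-count scaling the calls of Hsp68 (log2 -0.94), Hsp27 (-0.96), Hsp23 (-0.88), GstE10 (-0.96), Tps1 (-0.92) and CG1942 (-0.78) ended. JAK-STAT genes were at 0.20 (percentile 97.5), with TotC 3.47-fold higher and TotM 7.15-fold lower. The remaining lists were insulin, TOR and AKH at -0.05 (percentile 32.1), secreted factors at 0.09 (86.4), the TCA cycle at -0.14 (21.95), oxidative phosphorylation at -0.14 (9.48), intestinal epithelium at -0.10 (38.5), immune effectors at 0.04 (56.0, but 99.63 with a read minimum of 10 and 99.91 on the RPKM scale), the clock at -0.20 (3.6), autophagy at -0.05 (57.1), antioxidant genes at -0.13 (15.7), ovary and eggshell at 0.07 (51.3), haemocytes at 0.14 (79.5) and cuticle at -0.31 (6.59). Leaving out 1279 genes more abundant in other tissues left 112 higher genes in place of 175 and 196 lower in place of 250. Dscam4, mwh, Lsd-1, Tps1, CG32302, CG32834, ITP, Cyp6t3, Cyp6g1, Hsp68, GstE10, Try29F, Hs3st-A and kon overlap another coding gene and are uncertain.

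The carcass library of foxo RNAi flies held fewer transcripts of several genes of lipid synthesis, lipid mobilisation and the clock and more of eggshell proteins and of some antibacterial peptides. FASN1, fatty acid synthase, was 3.06-fold lower (3.02 to 3.09), the perilipin Lsd-1 3.86-fold (3.76 to 3.97), and AkhR, the receptor of adipokinetic hormone, 2.36-fold (2.22 to 2.50). The clock-controlled transcription factor genes vri (3.42-fold, 3.15 to 3.73), Pdp1 (2.47-fold) and cwo (2.46-fold) were lower. The antibacterial peptide gene Dro was 18.5-fold higher (16.6 to 20.9) and Dpt 7.63-fold higher (7.13 to 8.18). In the same libraries, photoreceptor genes were lower, led by the rhodopsin ninaE with 11546 and 22 reads (490-fold, 331 to 799). The labels name carcass as fat body, but its 2 libraries also differed in eye, neuron, gut and eggshell transcripts, so differences in fat body are not separated here from differences in dissection.

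Of 8589 genes compared in carcass, 293 were higher and 877 lower, so 25.0% of calls were higher. With total-count scaling the median of all genes moved up by 0.167 (log2) and 41.8% of calls were higher, and on the RPKM scale 42.9% were. The largest differences upward were in Osiris genes, which are expressed in forming cuticle, and in genes such as dyl, a zona pellucida protein of the apical matrix, and TwdlF, a cuticle protein. Osi6 had 0 and 1735 reads, at least 606-fold higher against the floor of 3 counts, with an exact interval starting at 493-fold. Osi20, ImpE2 and Np, also at 0 in the control, were at least 61.5-fold, 80.0-fold and 36.7-fold higher against that floor. Osi7 had 2 and 1567 reads (657-fold, 227 to 6789), Osi14 3 and 199 (59.8-fold, 23.5 to 340.1), and TwdlF 2 and 241 (101-fold, 34.6 to 1049). For dyl (374 reads), Osi15 (166) and mas (127), the control library held 1 read each, and the intervals of the ratios start at 70.0, 30.8 and 23.5. The numbered genes CG31813 and CG3397 had 0 control reads and were at least 167-fold and 155.9-fold higher against that floor.

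The genes with the largest differences downward in carcass belonged mostly to the eye. Arr1 was 365-fold lower, trpl 137-fold and chp 125-fold. For trp and ninaC, with 1 and 2 foxo RNAi reads, the ratios were 669 and 415 with intervals starting at 180 and 143, and Rh3 and inaC, at 0 reads, were at least 159-fold and 75.7-fold lower. Of 18 measured photoreceptor markers, a list chosen after values were seen, 16 were lower, and their summed level was 1559 CPM in the control and 98.6 CPM in the foxo RNAi library. Muc68D (114-fold), CG14125 (160-fold) and Obp99b (55.6-fold) were lower too, and CG10154, at 0 reads, was at least 82.7-fold lower.

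Lipid lists stood below their random lists in carcass. Triglyceride synthesis and storage had a median of -0.75 (percentile 0.01) with 10 of 26 lower, including CG1942 (10.7-fold), FASN1, Lsd-1 and Men, the NADPH-producing malic enzyme (2.84-fold). Lipolysis and fatty acid oxidation was at -0.66 (percentile 0.01) with 5 of 20 lower, among them CG5966 (6.43-fold), Lip4 (2.41-fold), AkhR and yip2 (2.28-fold). Lipoproteins were at -0.78 (percentile 0.23) with 4 of 12 lower, among them the lipid transfer particle Apoltp (2.92-fold) and the lipophorin gene Rfabg (2.14-fold). Fat body markers were at -0.84 (percentile 0.04) with 6 of 14 lower, such as Lsp1beta (6.75-fold). Foxo targets were at -0.60 (percentile 0.08) with Lip4, AkhR and Nmdmc (2.27-fold) lower among 17, and at percentile 1.15 without the most extreme member.

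The circadian clock list was at -0.54 (percentile 0.31) with vri, Pdp1 and cwo lower among 13. Cytochrome P450s were at -0.71 (percentile 0) with 19 of 53 lower, such as Cyp4e3 (4.10-fold) and Cyp28a5 (3.69-fold), and 2 higher, Cyp6a23 (2.20-fold) and Cyp12d1-d. Secreted factors were at -0.44 (percentile 0.46) with CNMa 2.75-fold lower among 25, and at 1.43 on the RPKM scale. CCHa2, a nutrient-sensitive peptide of the fat body and gut, was 3.26-fold lower within an enteroendocrine list at -1.19 (percentile 1.40). Immune effectors were higher for 8 of 31, including AttA (3.69-fold) and DptB (3.46-fold), and lower for 3, including Drsl4 (3.93-fold) and AttD (3.17-fold). Their median had the opposite sign to most calls, -0.25 (percentile 3.65). Ribosomal proteins stood above at 0.07 (percentile 99.98), with RpS5b, a paralogue abundant in the germ line, 2.74-fold higher among 82.

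Markers of other tissues moved strongly in carcass beside these groups. Ovary and eggshell genes were at 1.02 (percentile 100), with 13 of 22 higher, including the chorion genes Cp19 (22.6-fold), Cp16 (10.4-fold) and Cp18 (5.85-fold) and the vitelline membrane gene Vm26Aa (2.81-fold). Digestive enzymes were at -2.23 (percentile 0) with 25 of 33 lower, Jon65Ai by 42.0-fold and Jon99Fii by 33.1-fold. Neurons were at -2.04 (percentile 0) with 13 of 18 lower, such as the sodium channel gene para (13.4-fold) and Syt1 (7.92-fold). On the RPKM scale para did not pass the size rule, at a log2 of -0.44. Female tract genes were at -1.21 (percentile 0) with 6 of 11 lower, such as Send2 (11.6-fold) and CG17234 (6.01-fold), and Malpighian tubule genes at -0.83 (percentile 0) with 4 of 17 lower, such as CG7442 (3.29-fold) and CG9990 (2.22-fold). Sarcomere genes were at -0.02 (percentile 53.6), with Act88F (4.73-fold), sls (2.20-fold) and Strn-Mlck (2.03-fold) lower among 25. With total-count scaling the calls of sls (log2 -0.97), Strn-Mlck (-0.85), Rfabg (-0.93) and CG9990 (-0.99) ended.

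The remaining lists in carcass did not stand apart, although some did under alternatives. These were insulin, TOR and AKH at -0.13 (percentile 14.0), JAK-STAT at 0.13 (78.6) with chinmo (4.42-fold) and TotC (2.24-fold) higher and vir-1 2.35-fold lower, glycolysis at -0.44 (2.27) with Tps1 2.26-fold lower, the TCA cycle at -0.13 (33.6), oxidative phosphorylation at -0.14 (16.9), intestinal epithelium at -0.29 (26.3), heat shock at 0.19 (91.4), autophagy at -0.15 (18.04), proteasome at 0.12 (89), glutathione transferases at -0.33 (1.35, and under percentile 1 with 3 alternatives) with GstD10 4.39-fold lower, antioxidant genes at -0.44 (1.19, and under percentile 1 with 5 alternatives), haemocytes at -0.27 (8.71), cuticle at -0.56 (4.72) with kkv, the chitin synthase, 8.29-fold higher and Cpr72Ec 76.9-fold lower, and oenocytes at -0.67 (2.06). Lists with fewer than 5 measured members were not placed. Histones had 4 members with medians of 0.07 in thorax, 0.02 in gut and 0.12 in carcass, and pigment and transgene marker genes 2 members with medians of 0.61, -0.02 and -0.60. Salivary gland and crop genes had medians of 0.25, 0.51 and -0.55 from 3, 3 and 2 members. Of accessory gland and testis genes, Mst57Db had 0 and 31 reads in thorax, at least 5.09-fold higher, and Acp53C14a was 3.12-fold lower in carcass. Leaving out 927 genes more abundant in other tissues left 523 lower genes in place of 877 and 282 higher in place of 293. Lsd-1, Nmdmc, Rfabg, Tps1, DptB, trpl, para, CG7442, kkv and Strn-Mlck overlap another coding gene and are uncertain.

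**Figure D3:**
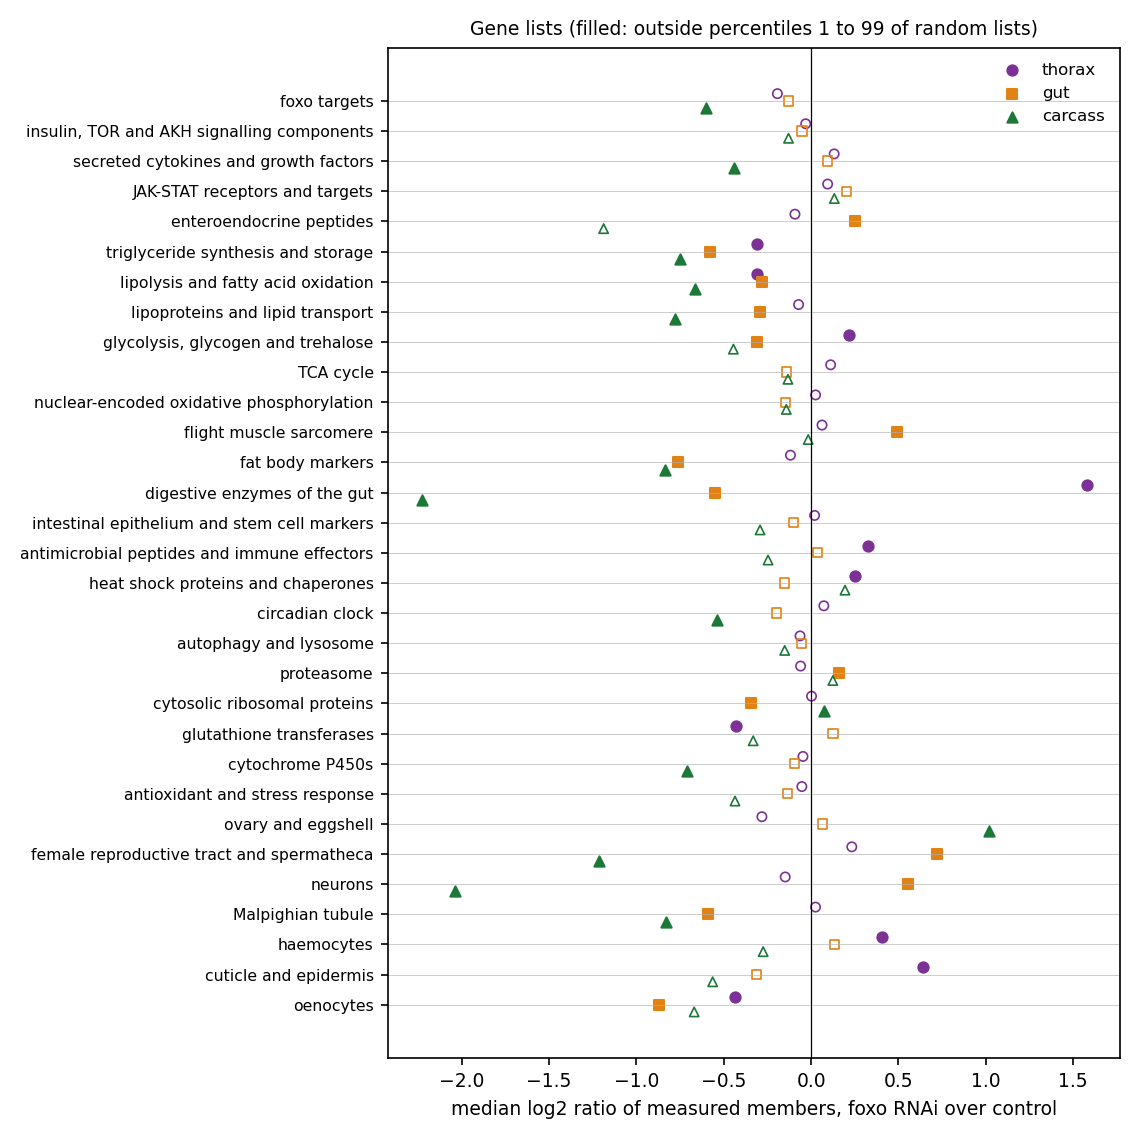
Points show the median log2 ratio, foxo RNAi over control, of the measured members of each gene list in thorax (circles), gut (squares) and carcass (triangles), 1 library per genotype, with filled points for lists under percentile 1 or over percentile 99 of matched random lists. Triglyceride synthesis and storage is filled and below 0 in each tissue (-0.31, -0.58 and -0.75), and digestive enzymes lie at 1.58 in thorax, -0.55 in gut and -2.23 in carcass.

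Some genes differed the same way in all 3 tissues. The cytochrome P450 genes Cyp6a23 and Cyp12d1-d, the stress peptide TotC, the tubulin betaTub60D and the numbered genes CG32302, CG3397 and CG12224 were higher in each, and Tektin-C, Dscam4, Alp2, Lsp1beta, CG17751, CG11893, CG8147, CG13091 and CG32750 lower. Tektin-C had 1007 and 31 reads in thorax, 87 and 5 in gut, and 83 and 5 in carcass. Cyp12d1-d has a close copy that can share its reads and is uncertain. On the RPKM scale the calls of Dscam4 in gut (log2 -0.59) and of Cyp12d1-d in thorax (1.47, but under a minimum of 1 RPKM) ended. CG3397 had 0 and 724 reads in thorax, 1 and 50 in gut, and 0 and 446 in carcass. In all, 10 genes were higher in every tissue, against 0.0494 for independent lists, and 19 were lower in every tissue, against 0.297. Leaving out genes more abundant in other tissues left 3 and 5.

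Between pairs of tissues, thorax and gut shared 33 higher genes (4.60 for independent lists) and 30 lower genes (4.29). Thorax and carcass shared 27 higher (5.30) and 68 lower (19.4), and gut and carcass 20 higher (2.36) and 101 lower (16.6). The largest opposite group was of 85 genes higher in thorax and lower in carcass (23.0), which included Muc68D, ninaE and CG14125. Without genes more abundant in other tissues, opposite calls between thorax and carcass dropped from 91 to 5. This filter leaves out tissue-restricted genes by construction, and no number for independent lists was computed after it. Each tissue has its own control library, but the same pair of genotypes is compared in each.

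The tissues were also compared with each other over both genotypes, which shows what each dissection held. In thorax, Act88F had a mean of 4831 CPM over 2 libraries, 540-fold above gut (adjusted p = 0.00184, edgeR) and 1302-fold above carcass (adjusted p = 0.00359). The giant muscle protein genes sls and bt were 134-fold and 66.7-fold above gut (adjusted p = 0.000828 and 0.00113). In gut, the digestive proteases Jon65Aiv and alphaTry were 438-fold and 383-fold above thorax (adjusted p = 0.00908 and 0.00935). In carcass, the vitelline membrane genes Vml and Vm26Ab were 4826-fold and 4766-fold above thorax (adjusted p = 0.00121 and 0.00126), and the lipid gene FASN2 was 84.5-fold above gut (adjusted p = 0.000602).

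Of 9293 genes tested, 2614 were higher in thorax than in gut and 2459 the reverse, 2031 higher in thorax than in carcass and 1796 the reverse, and 1921 higher in gut than in carcass and 2115 the reverse. Above both other tissues were 1456 genes in thorax, 1382 in gut and 768 in carcass. The genes with the largest fold over both were Act88F, CG15617, CG4461, CG2022 and CG34172 in thorax, CG10477, CG9682, LManVI (an alpha-mannosidase), CG31265 and CG15533 in gut, and Vml, Vm26Ab, ndl, CG4009 and dec-1 in carcass. Leaving out the control gut library moved thorax over gut to 1556, gut over thorax to 1265, carcass over thorax to 1163, gut over carcass to 998 and carcass over gut to 1033, and leaving out the foxo RNAi gut library moved the comparisons with gut to 1731, 1389, 998 and 1093. Thorax over carcass and carcass over thorax moved to 1312 and 1046 without the foxo RNAi thorax library and to 1086 and 997 without the foxo RNAi carcass library, and carcass over thorax to 1147 without the control thorax library.

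Cell type lists placed the dissections. Sarcomere genes were higher in thorax than in both other tissues for 24 of 27 tested members, and neuron genes for 18 of 18. Digestive enzymes were higher in gut than in both for 37 of 42, and intestinal epithelium markers for 7 of 13, including Myo31DF (12.4-fold over carcass, adjusted p = 0.00142). Ovary and eggshell genes were higher in carcass than in both for 19 of 22, and female tract genes for 6 of 11. Fat body markers were higher in carcass than in gut for 12 of 15, but 12 of 15 were also higher in thorax than in gut, and 1 differed each way between thorax and carcass. Haemocyte genes were higher in thorax than in both for 8 of 16, and cuticle genes for 5 of 14. Oenocyte genes were higher in carcass than in gut for 7 of 8, and Malpighian tubule genes were higher in gut than in thorax for 11 of 17 and in carcass than in thorax for 10 of 17. Of 4 salivary gland and crop genes, 3 were higher in gut than in carcass, and the only accessory gland and testis gene tested was higher in carcass than in thorax.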

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

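The tests of Hsp70Bb, of gut transcripts in thorax and of genes shared by all 3 tissues against independent lists were chosen after the results were seen, and the test for a linked chromosome segment was written before its value was seen. The widened intervals for gut shares, and the bars set for upd2 and Muc68D, were put in place of earlier versions after the values of those were seen.

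Gene groups that are higher in the foxo RNAi library of 1 tissue and lower in that of another stood out, although no difference between tissues was tested. In thorax and gut, 22 genes were higher in thorax and lower in gut (6.16 for independent lists), and 7 the reverse (3.20). In thorax and carcass these numbers were 85 (23.0) and 6 (4.47), and for genes higher in gut and lower in carcass, and the reverse, they were 31 (11.4) and 2 (3.42), so the groups of 6 and 2 were near or below that number. Digestive enzymes had median log2 ratios of 1.58 in thorax, -0.55 in gut and -2.23 in carcass. Glycolysis, glycogen and trehalose genes were at 0.21 in thorax and -0.31 in gut. Ribosomal proteins were at -0.35 in gut and 0.073 in carcass. Female tract genes were at 0.72 in gut and -1.21 in carcass, and neuron genes at 0.55 in gut and -2.04 in carcass.

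Gut transcripts in the foxo RNAi thorax library, such as Muc68D with 38 control and 38413 foxo RNAi reads, may come from gut tissue or from a response of the thorax. RNA of whole gut mixed in at a fixed share would give each gut gene about the same share of its gut level. CPM were scaled within each tissue, so the absolute shares are approximate. An error in scale between tissues would change all shares by the same factor and leave their order as it is. The shares ran from -0.60 to 43.3% around a pooled 1.98%, which 100% of 40 genes left out by counting intervals alone (36 of 39 without Muc68D, pooled 0.955%), but the 2 gut libraries themselves differed by up to 7.53-fold in these genes, and with intervals widened by that factor the best single share left out 17.5%. Whole-gut RNA is argued against as the source of the upd2 reads, which need a share of 88.2% (interval from 56.5%). With shares widened in the same way, 77.5% of 40 gut genes stayed below that share. The Muc68D reads need 43.3%, and 59.0% of 39 other gut genes stayed below that. Muc68D was picked from these data and has the highest share of the 40, so the others lie below it by selection. Its test therefore cannot decide the source of its reads. For the gut genes, Muc68D included, whole-gut RNA mixed in at a fixed share cannot be told apart from a response of the thorax. For upd2 and all gut genes a piece of a single gut region cannot, because levels per gut region were not used here.

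The Hsp70Bb reads of the foxo RNAi thorax library, 43222 against 24, may reflect a heat shock response, counting between copies or the transgene. The other inducible heat shock genes had a median log2 ratio of 0.52 (range -0.66 to 0.94), and none passed the size rule, against 869-fold for Hsp70Bb. A broad rise of these genes was thus not seen. How far they rise beside Hsp70Bb in a heat shock was not measured, so these values do not settle whether such a response took place. The summed level of the 6 Hsp70 copies was 527.5-fold higher (392.2 to 748), so an exchange of reads between copies is argued against. A candidate explanation is transcription of the RNAi transgene, since UAS vectors commonly carry Hsp70 promoter sequence: where the driver is not named as active, Hsp70Bb had ratios of 2.45 in carcass (1.16 to 5.90) and 0.899 in gut (0.744 to 1.09). The vector is not given in the sources used here, and a response of Hsp70Bb alone to the foxo hairpin in thorax stays open as untested.

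For independent lists, 0.346 genes called the same way in all 3 tissues would be found, against 29 here. These genes may mark different genetic backgrounds of the lines, a difference in collection between the genotypes or a response of every tissue. Such causes cannot be told apart, because the same pair of genotypes was compared in each tissue. Differences in dissection common to the tissues were not tested for these genes either. A single linked chromosome segment holding these genes as a set is argued against: 5 pairs of them lay within 1 Mb of each other, against a median of 7 in 10000 random sets, at percentile 22.7. The test cannot exclude a segment that holds only a few of them. CG12224 and CG3397, both higher in each tissue, lie close together on 3R (11980704 to 11982622 and 11983098 to 11984541). Without genes more abundant in other tissues, 3 higher and 5 lower genes were left.

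Genes listed at 0 counts with an RPKM above 0, most of them non-coding, gave a signal outside the comparisons made on counts. After reads were recovered from RPKM, 13 of 226 such genes were higher and 24 lower in foxo RNAi thorax, 5 and 13 of 113 in gut, and 10 and 18 of 122 in carcass. Higher were, among others, CR44948 (5 and 234 reads) and CR45284 (0 and 74 reads) in thorax, CR40469 (49 and 306 reads) in gut, and the dosage compensation RNA roX1 (30 and 141 reads) in carcass. Lower were, among others, CR45372 (111 and 15 reads) in thorax and CR44662 (124 and 17 reads) in carcass. In gut, the lower genes with the largest near bounds were ribosomal RNA pseudogenes. Examples are 28SrRNA-Psi:CR45859 (27885 and 6310 reads) and 18SrRNA-Psi:CR41602 (14225 and 3582 reads), and the cause was not tested.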

How the results depend on the processing

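Over all alternatives run, 174 main results were kept and 60 moved, where a number of genes or lists is kept within 1.5 times and a foxo or upd2 ratio within its 95% counting interval. No foxo, upd2 or named gene ratio changed direction, and no list that stood apart crossed percentile 50. The balance of calls did turn: in gut from 175 higher and 250 lower genes to 333 and 172 with total-count scaling and 231 and 145 on the RPKM scale, and in thorax from 316 and 242 to 143 and 187 without genes more abundant in other tissues. Thorax and carcass calls went from 95 in the same and 91 in opposite directions to 70 and 77 on the RPKM scale. Values of named genes kept their side of the size rule in 1841 cases and lost it in 189, and on the RPKM scale these included yl and Tep1 in thorax, vn, Hs3st-A, bt, Dscam4, ZnT35C and FASN3 in gut, and Np, chinmo, kkv, Nmdmc, Pdp1 and para in carcass. With a read minimum of 100, only 224 values were scored, against 258 with a minimum of 10. Named genes that fell under the minimum of 100 are not among the 189. List placements were lost in 17 cases, gained in 20 and unchanged in 688. The unchanged cases include lists that stood apart in neither setting, so they are not all placements kept. Gained in carcass were antioxidant genes (percentile 0.965 with total-count scaling, 0.35 on the RPKM scale, 0.995 and 0.41 with read minimums of 10 and 100, 0.82 after loess), glutathione transferases (0.09 on RPKM, 0.45 and 0.19 with minimums of 10 and 100), enteroendocrine peptides (0.27 on RPKM, 0.01 with a minimum of 10, 0.77 after loess), glycolysis (0.87) and histones (99.32) on RPKM, and cuticle genes (0.54) with a minimum of 10. In gut these were immune effectors (99.63 with a minimum of 10, 99.91 on RPKM), glutathione transferases (99.58) and salivary gland genes (99.96) on RPKM, and in thorax cytochrome P450s (0.44) with a minimum of 10 and accessory gland genes (99.99) on RPKM. DESeq2 size factors, a read minimum of 10, recovered reads, loess, RLE factors, the DESeq2 Wald test, no expression filter and no genotype covariate moved no main result. Leaving out coding genes that overlap another, an alternative added after seeing the data, as recovered reads and leaving out genes of other tissues were, moved none either.

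A rule of 1.5-fold with a bound of 1 gave 730 higher and 692 lower genes in thorax, 602 and 668 in gut, and 1182 and 1692 in carcass. A rule of 3-fold with a bound of 2 gave 205 and 85, 67 and 102, and 121 and 388. These follow from the looser and stricter thresholds. Total-count scaling gave 333 higher genes in gut, 478 in carcass and 16 in all 3 tissues, and foxo ratios of 0.761 in thorax, 0.921 in gut and 0.857 in carcass. The RPKM scale gave 154 lower genes in thorax, 145 in gut, 468 in carcass and 11 in all 3 tissues, foxo ratios of 0.780, 0.936 and 0.876, and upd2 ratios of 2.75 in thorax and 0.721 in carcass. Total-count scaling differed from the main setting only in using no TMM factors. The RPKM scale also used none, added 0.5 to each value and needed at least 1 RPKM for a call. The added 0.5 shrinks ratios of low genes by construction: with total-count scaling the upd2 ratio in thorax was 5.215. Beyond the shift of the median of all genes, the part played by each step was not tested. With a read minimum of 100, fewer genes enter: 2 lists stood above in gut, thorax and gut shared 41 genes in the same direction, and opposite calls were 56 for thorax and carcass and 17 for gut and carcass. Without genes more abundant in other tissues, 143 genes were higher in thorax, 112 higher in gut and 523 lower in carcass. Same-direction calls were then 19 for thorax and gut and 54 for gut and carcass, opposite calls 6, 5 for thorax and carcass, and 8 for gut and carcass, and 3 and 5 genes were higher and lower in all 3.

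Between tissues, the test against a fold of 2 left 1270 genes higher in gut than in thorax, 944 in thorax over carcass, 665 in carcass over thorax, 1018 in gut over carcass and 1249 in carcass over gut. Leaving out each library in turn, thorax over gut ranged from 1556 to 2700 genes, gut over thorax from 1265 to 2666, thorax over carcass from 1086 to 1738, carcass over thorax from 997 to 1724, gut over carcass from 998 to 1902 and carcass over gut from 1033 to 2153. Moves of over 1.5 times came from losing the control gut (1556, 1265, 1163, 998, 1033), foxo RNAi gut (1731, 1389, 998, 1093), foxo RNAi thorax (1312, 1046), foxo RNAi carcass (1086, 997) or control thorax (1147) library, each of which leaves a tissue with 1 library that is assumed to vary like the others. The labels give no replicate numbers, so no paired fit followed from them. Genotype was a covariate in the tissue test, and a genotype effect common to the tissues was not tested. An alternative with reads mapped to several places was not run, since a single count per gene was used here. With 24 and 65 reads, upd2 in gut had an interval of 1.45 to 3.93, which spans the bound of 1.5.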

Other observations

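In 3 genes abundant in thorax, the other tissues differed in opposite ways, and these genes were chosen after their values were seen. CG16826, lcs and CG1678 are among the most abundant genes of the thorax, where CG16826 had 412004 control reads, and none was past the size rule there. In the foxo RNAi gut library they were 29.6-fold (26.3 to 33.6), 14.1-fold (12.4 to 16.2) and 37.9-fold (30.1 to 49.0) higher. In the foxo RNAi carcass library they were 35.3-fold (29.4 to 43.1), 35.2-fold (26.4 to 49.2) and 42.1-fold (31.4 to 59.3) lower. Act88F, specific to flight muscle, had 45 and 107 reads in gut, a ratio of 2.05 (1.44 to 2.99), and was 4.73-fold lower in carcass. Sarcomere genes as a list were at 0.49 in gut but at -0.02 in carcass (percentile 53.6).

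Other genes chosen after their values were seen bear on hormones and the clock. The clock genes Clk, tim and per had ratios of 0.534 (0.473 to 0.601), 0.612 (0.565 to 0.663) and 1.09 (0.931 to 1.29) in carcass, and none of them passed the size rule. The alpha-glucosidase gene tobi, a target of insulin-like peptides and of adipokinetic hormone, was 2.95-fold higher in thorax (2.36 to 3.78) and 4.68-fold lower in carcass (4.15 to 5.29). It is also 1 of the 40 genes of the gut lists, with a share of 6.96% of its gut level in thorax, so its thorax value may come from gut tissue. ImpL2 had ratios of 1.70 in thorax (1.65 to 1.74), 2.11 in gut and 0.578 in carcass (0.546 to 0.612), of which only that in gut passed the size rule. Of 24 Osiris genes listed, 10 were measured in carcass and 9 of these were higher, with a median log2 ratio of 6.57. The 24 held 36 control reads together, so members reached the read minimum almost only through the foxo RNAi library. The number higher and the median follow largely from that filter. The summed level of the 24 was 2.44 CPM in the control and 301 CPM in the foxo RNAi library. Cyp12d1-d, at 0 control reads in each tissue, has a close copy, Cyp12d1-p, with 56 and 134 reads in thorax, 77 and 74 in gut, and 130 and 58 in carcass. In gut, reads recovered for ribosomal RNA pseudogenes were lower in the foxo RNAi library, such as 27885 and 6310 for 28SrRNA-Psi:CR45859.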
